A study of Macaca mulatta with 80 samples.

How the data were processed

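The values used were the log2 values deposited by the authors, 1 per probe set and array, for 54,675 probe sets on 80 arrays. They ran from 3.42 to 14.51. The algorithm that summarised the probes and any scaling between arrays are not given in the sources used here. Animals were 16 male rhesus monkeys, and total RNA taken with Trizol was labelled with biotin in 2 amplification cycles, so poly(A) RNA was read from its 3' end. The array was designed for human transcripts, so a probe that differs from the macaque sequence reads low at any age. The lower quartile, median and upper quartile of the arrays spread over 0.120, 0.106 and 0.120, above the limit of 0.05 set before the data were examined. All 80 arrays were therefore quantile normalized together in limma 3.58.1 (R 4.3.3), and the values as deposited became an alternative.

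Of the probe sets, 62 were controls, 41,091 had 1 gene symbol, 1,801 had several and 11,721 had none. Only those with 1 symbol were used, with the probe set of the highest mean over all arrays standing for the gene, and none were left out for low signal. This gave 19,775 genes tested, with a median of gene means of 5.98. No array was left out. The highest correlation between 2 arrays was 0.995 and 0 pairs were identical.

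Age effects over the 5 regions were fitted with limma (lmFit, eBayes) on the mean of the 5 regions of each monkey number, so n = 4 per age, and all 4 ages shared 1 estimate of the spread. Age effects within a region used the 16 arrays of that region. Region effects were fitted on the difference of a region from the mean of the other 4 regions of the same number, averaged over the ages. The same differences, adult minus newborn, tested whether an age effect differed between regions. A limma F test of the region by age terms used the number as a random block with a duplicateCorrelation of 0.0576. P-values were adjusted by Benjamini-Hochberg over the 19,775 genes within a comparison, and genes past 0.05 were called. An SE is that of the limma contrast after eBayes, and changes are log2 differences, first group minus second.

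In all, 36 gene lists were tested with limma camera at a preset correlation between genes of 0.01, with adjustment over the 36 lists of a comparison, and again with an estimated correlation. The adjusted p of a list is from camera, and counts of members called are from the gene tests. The designs, lists, thresholds, alternatives and rules for naming genes were fixed before the data were examined. The rule for naming genes took, for adult against newborn over 5 regions, the 10 largest rises and 10 largest falls among called genes with the same sign in all 5 regions and the higher mean above the median of genes tested. It took 4 of each for an age step, 5 highest and 2 lowest for a region with the same sign at all 4 ages, 3 of each for an age effect that differs between regions, and up to 4 members of each list with the smallest p. Uncharacterised loci were passed over, and there were no other exceptions.

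Whether the numbers mark animals was examined by the correlation, between regions, of each array's deviation from its group. Arrays of the same number had a mean correlation of 0.163 and those of other numbers of the same age −0.054, with 104 of 160 pairs (65%) over 0.1 and 108 whose best match had the same number. The one-sided permutation p was 5e-04, the smallest that 2000 permutations can give here.

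The tests were tried on simulated values with 200 changed genes among 19,775. At a change of 0.5 log2 and of 1 log2, 98% and 100% were recovered for age over 5 regions, 59% and 99% for age in 1 region, and 99% and 100% for a region effect. For a regional age effect they were 50% and 99%, and for the F test 24% and 95%. False calls were 11, 7, 15, 11 and 13. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.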

Results

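Gene expression was measured in 5 parts of the hippocampal formation of 16 male rhesus monkeys: the entorhinal cortex (EC), the dentate gyrus (DG), CA3, CA1 and the subiculum (Sub). There were 4 newborn (1 day), 4 6-month, 4 one-year and 4 adult (6 to 12 years) animals, and each region of each animal was read on its own array, which gave 80 arrays in 20 groups of 4. Main comparisons and gene lists were fixed before the data were examined. Values below are log2 signals after quantile normalization. The comparisons that leave out CA1 and CA3, and those with newborn arrays only, were chosen after the RNA quality below was seen.

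RNA quality was read from control probe sets at the 3' and 5' ends of GAPDH, whose log2 ratio rises when long RNA is lost. In CA1 the mean ratio was 1.38 in newborns, 2.38 at 6 months, 3.16 at one year and 2.75 in adults. In CA3 it was 1.14, 1.09, 1.16 and 2.74 at the same ages. It lay between 1.04 and 1.35 in DG, 1.40 and 1.69 in EC, and 1.34 and 1.60 in Sub, with single high arrays in EC at one year (number 8, 2.69) and in adult Sub (number 4, 2.72). In DG it was higher at one year and in adults (1.30 and 1.35) than in newborns (1.06). The first principal component held 27.0% of the variance and had a correlation of −0.92 with the ratio. The actin 3'/5' ratio, read in the same way, had a correlation of 0.499 with that of GAPDH over the 80 arrays. Its means were 3.80, 3.68, 4.06 and 4.22 in CA1 and 3.58, 3.57, 3.65 and 4.43 in CA3, so it rose in adult CA3 but not in CA1 at 6 months. EC number 8 had a low actin ratio (2.48 against 3.78 to 4.03), and Sub number 4 a high one (4.55 against 3.25 to 3.98). By the GAPDH ratio CA1 after birth and adult CA3 are read below beside DG, EC and Sub, though for many list members only the change over 5 regions is given.

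**Figure D1:**
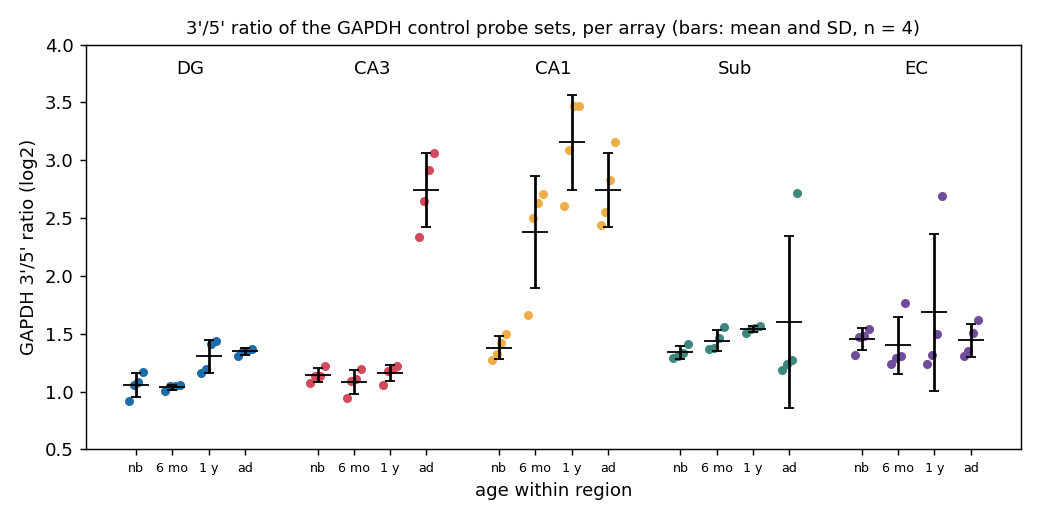
GAPDH 3'/5' log2 ratio of each of the 80 arrays by region and age, n = 4 arrays per group. The mean ratio was above 2 in CA1 from 6 months on, where number 12 at 6 months alone was lower (1.66), and in CA3 in adults.

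Between birth and adulthood genes of immature neurons and neurite outgrowth fell in the hippocampal formation. SOX4 and SOX11, transcription factors of young neurons, DPYSL3 and the matrix gene TNC were among those lower in every region, and VAMP1 and ENPP2 among those that rose. Over the 5 regions 5484 of 19,775 genes changed, 2808 higher and 2676 lower in adults. Over DG, EC and Sub alone 2612 genes changed (1174 higher, 1438 lower), of which 2186 were also called over all 5. With the ratio as covariate 527 genes changed over the 5 regions. The ratio of CA1 and CA3 was itself higher in adults than in newborns, so the lost calls decide little. The share of calls that were higher was 51.2%, and 37.9% with values as deposited or 29.2% with each array centred on its median.

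The largest falls over 5 regions were those of YBX1, TNC and SOX4. Over DG, EC and Sub YBX1 fell less than TNC, SOX4 (−2.27), DPYSL3 (−2.20), SOX11 (−2.12) and COL3A1 (−1.95). YBX1, which codes for a protein that binds RNA and DNA, fell by 2.67 (SE 0.122, n = 4 per age, adjusted p = 2.05e-10), from 12.21 ± 0.050 (SD) to 9.55 ± 0.283, and by 1.89 over DG, EC and Sub, with 1 of 2 other probe sets moving the same way. TNC, the matrix protein tenascin-C, fell by 2.58 (SE 0.117, adjusted p = 2.05e-10), from 8.74 to 6.16, and by 2.50 over DG, EC and Sub, with 1 of 2 other probe sets the same way. SOX4 fell 5.49-fold, from 9.97 ± 0.113 to 7.52 ± 0.283 (SE 0.101, adjusted p = 1.08e-10). Its relative SOX11, also a transcription factor of newly formed neurons, fell by 2.01 (SE 0.085, adjusted p = 1.08e-10). FABP7, the fatty acid binding protein of radial glia, fell by 2.01 and by 1.52 over DG, EC and Sub. DPYSL3, which codes for a growth cone protein, fell by 1.90 (adjusted p = 1.87e-09; 1 of 2 other probe sets the same way), and NREP by 1.89. COL3A1, a fibrillar collagen, fell by 1.77 (adjusted p = 1.33e-05). The neuropeptide gene NTS fell by 1.69, and by 0.96 over DG, EC and Sub. CCDC80 fell by 1.68, with 1 of 2 other probe sets the same way.

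Among genes that rose, PLEKHA2 gained most over 5 regions, 1.63 (SE 0.107, n = 4 per age, adjusted p = 1.66e-08), from 8.50 ± 0.138 to 10.13 ± 0.112. Over DG, EC and Sub it gained 1.40, less than ETNPPL at 1.57. GSKIP, whose product binds GSK3 beta and protein kinase A, rose by 1.56 (SE 0.095, adjusted p = 5.89e-09) and by 1.54 over DG, EC and Sub. ETNPPL, an astrocyte enzyme of lipid breakdown, rose by 1.51 and AKR1C1, which reduces steroids, by 1.48. CCDC28A rose by 1.47 (SE 0.074, adjusted p = 7.28e-10), EFEMP1, a matrix protein gene, by 1.41 and BBX by 1.35. VAMP1, a vesicle protein of synaptic release, rose by 1.34 and ENPP2, the oligodendrocyte enzyme autotaxin, by 1.33. ENPP2 was at 1.45 over DG, EC and Sub, and at 0.68 (adjusted p = 0.0748) over 5 regions with the ratio as covariate. RAP1GDS1 also passed at 1.43 (SE 0.388, adjusted p = 0.0102; 1 of 3 other probe sets the same way), but newborn number 15 alone lay low (7.36 against 9.53 to 9.94), and over DG, EC and Sub the change was 0.72 (adjusted p = 0.286). In CCDC28A, EFEMP1, BBX, SOX11 and NREP too, 1 animal of an age lay apart from the other 3.

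**Figure D2:**
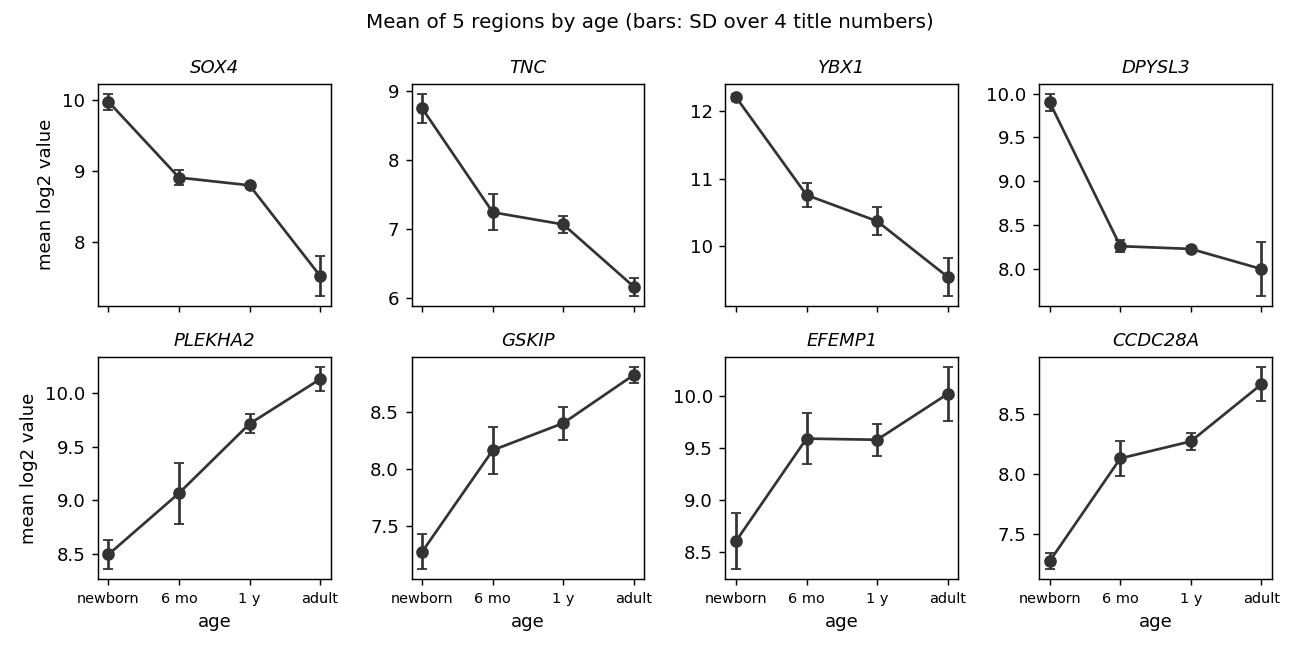
Mean log2 signal of 5 regions at each age for SOX4, TNC, YBX1, DPYSL3, PLEKHA2, GSKIP, EFEMP1 and CCDC28A. Bars are the SD over 4 animals.

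As a group, genes of immature neurons and neurite outgrowth fell most clearly: 19 of 24 measured members were lower in adults and 0 higher (22 lower when adjusted over the list alone; adjusted p = 1.3e-18). With an estimated correlation the adjusted p was 8.3e-05. DCX, the microtubule protein of migrating neurons, fell by 1.28 beside SOX4, SOX11 and DPYSL3. Oligodendrocyte precursor genes fell too, with 6 of 13 lower and 1 higher (adjusted p = 0.00914; adjusted p = 0.368 with an estimated correlation), among them PDGFRA (−0.90), the growth factor receptor of these cells, LHFPL3 (−1.12) and SOX6 (−0.89). Interneuron genes had 8 of 16 lower and 1 higher (adjusted p = 0.00596; adjusted p = 0.264 with an estimated correlation), with DLX1 and LHX6, transcription factors of developing interneurons, at −0.78 and −0.50 and the vesicular GABA transporter SLC32A1 at −0.56. Proliferation genes had 8 of 30 lower, among them CCND1 (−0.63) and CDC20 (−0.57) of the cell cycle (adjusted p = 0.0262; adjusted p = 0.264 with an estimated correlation).

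Collagen genes of meninges and fibroblasts had 7 of 16 members lower and 1 higher (adjusted p = 0.0141; adjusted p = 0.5 with an estimated correlation), led by COL3A1 and fibronectin, FN1 (−0.94). Of 15 cholesterol synthesis genes 6 were lower and 2 higher, with the enzymes NSDHL at −0.63 and EBP at −0.52 (adjusted p = 0.024; adjusted p = 0.5 with an estimated correlation). Subicular neuron genes had 5 of 10 lower (adjusted p = 0.0136; adjusted p = 0.264 with an estimated correlation). That list shares FN1 with the collagen list and ROBO1 with the immature neuron list, and holds NTS, so its fall is not independent of theirs. Myelin genes had 11 of 23 higher and 4 lower over 5 regions (adjusted p = 0.213), but 11 higher and 0 lower over DG, EC and Sub (adjusted p = 2.57e-08; adjusted p = 0.0552 with an estimated correlation). CNDP1, made by oligodendrocytes, rose by 1.16. MAG, the myelin-associated glycoprotein, fell by 0.82 over 5 regions and was at −0.09 (adjusted p = 0.76) over DG, EC and Sub, where no group mean of the ratio was above 1.69.

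Lists of receptor, channel and synaptic genes did not pass from newborn to adult, though single members changed. The list test asks for a shift in 1 common direction, so a list whose members move both ways can fail it. Of 36 lists 29 did not pass over 5 regions, with adjusted p from 0.0615 to 0.995. The synaptic vesicle list had 8 of 22 members higher and 4 lower (adjusted p = 0.449), and its median change of −0.03 and mean of 0.07 differed in sign. SNAP25 and SYT1, both of vesicle fusion, rose by 0.58 and 0.46. SLC12A5, the chloride exporter KCC2 of mature neurons, rose by 0.47. The potassium channels KCNA1 and KCND3 rose by 0.54 and 0.77 and the sodium channel SCN1A by 0.40, while SCN3A, the sodium channel of the developing brain, fell by 0.83. GABRA2 rose by 0.47 and GABRA3 fell by 0.42, both subunits of the GABA-A receptor. The glutamate receptor subunits GRIK3 and GRIN3A fell by 0.82 and 0.80. CAMK2A, the kinase of the postsynaptic density, rose by 0.40 and NRGN, the calmodulin-binding neurogranin, fell by 0.61. TGFB2 and FGF1 rose by 1.10 and 0.78, and IGF1, a growth factor of early life, fell by 0.95. IFIT1, an interferon response gene, rose by 1.28. These single-gene changes are over the 5 regions, CA1 and CA3 included, and may differ over DG, EC and Sub alone.

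Schizophrenia candidate genes, a list of 22 fixed here of which 20 were measured, included 2 that rose and 4 that fell (adjusted p = 0.309). DTNBP1, dysbindin, rose by 0.97 (adjusted p = 1.09e-06), and 0.90 over DG, EC and Sub. TCF4, a transcription factor, fell by 0.63 (adjusted p = 1.54e-05) and by 0.64 in those regions. NRG1 rose by 0.18 (adjusted p = 0.00579) over 5 regions, and was at 0.12 (adjusted p = 0.155) over DG, EC and Sub.

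**Figure D3:**
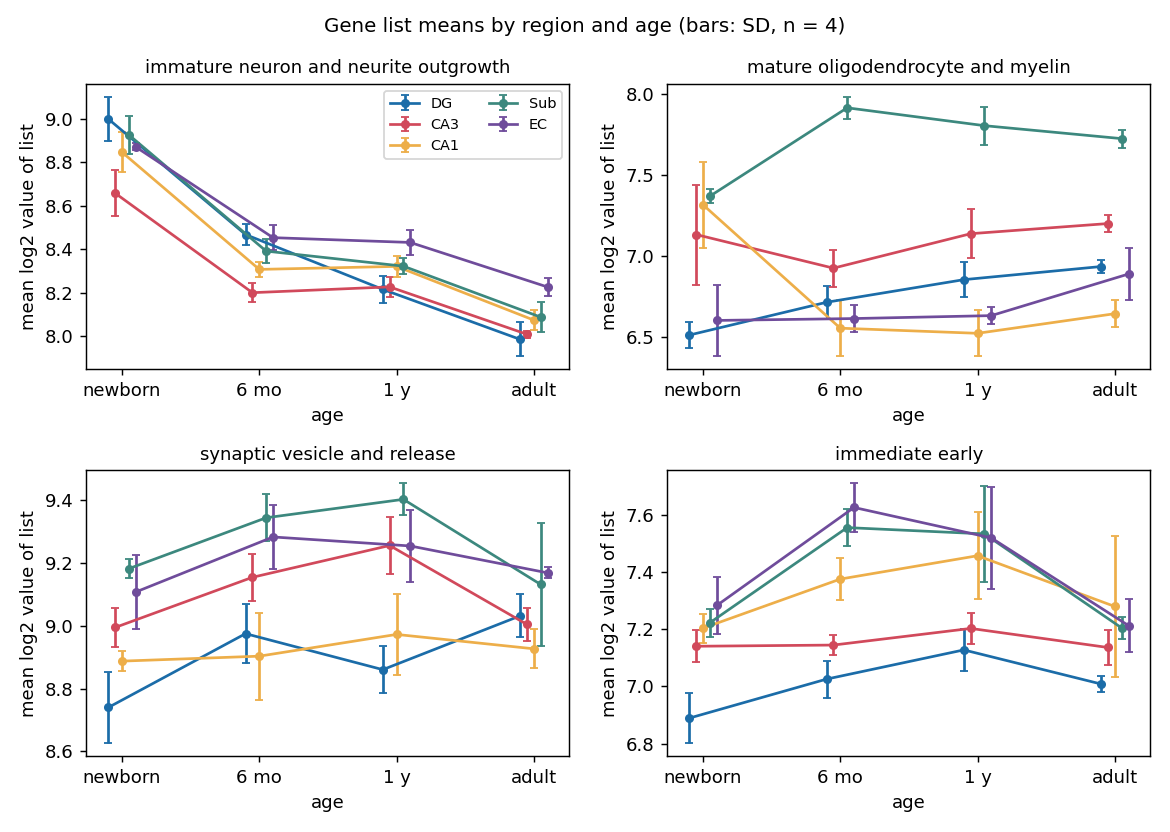
Mean log2 signal of 4 gene lists (immature neuron, myelin, synaptic vesicle, immediate early) by region and age. Bars are the SD over 4 animals.

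The first 6 months carried much of the loss of immature neuron genes and a gain of synaptic vesicle genes. Between newborn and 6 months 1598 genes changed, 665 higher and 933 lower (41.6% higher, and 20.1% as deposited or 15.6% centred on the median). Over DG, EC and Sub they were 851, 349 higher and 502 lower. DPYSL3 fell by 1.64 (SE 0.103, n = 4 per age, adjusted p = 1.13e-07), and so did TNC (−1.502), YBX1 (−1.45) and FABP7 (−1.11). EFEMP1 rose by 0.99 (adjusted p = 0.000324), ETNPPL by 0.93, GSKIP by 0.89 and CCDC28A by 0.86 (adjusted p = 3.71e-06). Immature neuron genes had 15 of 24 lower and 1 higher (18 and 1 when adjusted over the list alone; adjusted p = 3.85e-23), with DCX at −1.08. Interneuron genes had 7 of 16 lower (adjusted p = 2.85e-06) and proliferation genes 4 of 30 (adjusted p = 0.000604). Both passed with an estimated correlation (adjusted p = 0.0427 each). Synaptic vesicle genes had 11 of 22 higher and 1 lower (adjusted p = 2.2e-05; adjusted p = 0.0928 with an estimated correlation), among them SNAP25 (0.43), PCLO (0.53), SYT1 (0.35) and the vesicular glutamate transporter SLC17A7 (0.33). Immediate early genes, which neuronal activity switches on, had 3 of 14 higher and 1 lower (adjusted p = 0.00111; adjusted p = 0.0928 with an estimated correlation), with EGR4 at 0.59, EGR3 and EGR1 at 0.44 each, and IER2 at −0.24. Precursor genes had 6 of 13 lower (adjusted p = 0.000604; adjusted p = 0.168 with an estimated correlation), collagen genes 5 of 16 (adjusted p = 0.00518; adjusted p = 0.398 with an estimated correlation) and subicular neuron genes 3 of 10 (adjusted p = 0.0138; adjusted p = 0.169 with an estimated correlation). Of ribosomal protein genes 6 of 34 were lower (adjusted p = 0.00781; adjusted p = 0.617 with an estimated correlation). HSPH1, a chaperone, rose by 0.48 and was the only 1 of 9 heat shock genes called (adjusted p = 0.0262; adjusted p = 0.0982 with an estimated correlation). Myelin genes, which did not pass over 5 regions, had 5 of 23 higher and 0 lower over DG, EC and Sub (adjusted p = 9.89e-08; adjusted p = 0.037 with an estimated correlation).

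From 6 months to one year no gene of the 19,775 passed in limma over the 5 regions, while 1614 had an unadjusted p under 0.05. Within single regions 16 genes passed in DG (9 higher, 7 lower), 8 in CA1, 1 in CA3, 1 in Sub and 0 in EC. With the 80 arrays fitted together and the animal as a random replicate block, 56 genes passed over the 5 regions. Complement and MHC genes passed as a list (adjusted p = 0.0143; adjusted p = 0.629 with an estimated correlation), with 0 members called over all genes and 2 higher when adjusted over the list alone. B2M, the light chain of MHC class I, was at 0.51 (adjusted p = 0.305).

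After one year the immature neuron genes fell further and immediate early genes fell. Between one year and adulthood 833 genes changed, 350 higher and 483 lower (42.0% higher, and 18.8% as deposited or 13.5% centred on the median). Over DG, EC and Sub 154 changed, 69 higher and 85 lower, and the ratio of CA3 rose over this step. SOX4 fell by 1.28 (SE 0.101, n = 4 per age, adjusted p = 7.91e-06), TFRC, the transferrin receptor, by 0.92 (2 of 4 other probe sets the same way) and TNC by 0.90. FOS, an immediate early gene, fell by 0.75 (adjusted p = 0.00577), but by 0.57 (adjusted p = 0.0929) over DG, EC and Sub without numbers 4 and 8. MYLK, the kinase of myosin light chain, rose by 0.83 (adjusted p = 0.000799), SPMIP2 by 0.82 and RSRC1 by 0.82, the last with 0 of 2 other probe sets moving the same way and at 0.60 (adjusted p = 0.0547) over DG, EC and Sub without numbers 4 and 8. ANXA2 rose by 0.83 (adjusted p = 0.028), and was at 0.60 (adjusted p = 0.0835) over DG, EC and Sub. Immature neuron genes had 6 of 24 lower (10 when adjusted over the list alone; adjusted p = 5.96e-08, and 0.00495 with an estimated correlation). Immediate early genes had 5 of 14 lower, with JUNB at −0.56, DUSP1 at −0.41 and EGR4 at −0.45 (adjusted p = 0.0106; adjusted p = 0.421 with an estimated correlation). Synaptic vesicle genes had 3 of 22 lower, CPLX1 among them (−0.42), and 1 higher, VAMP1 (0.58), with adjusted p = 0.0166 and adjusted p = 0.714 with an estimated correlation. Ribosomal protein genes had 5 of 34 higher (adjusted p = 0.00651; adjusted p = 0.714 with an estimated correlation), with a median change of 0.09 that became −0.08 with each array centred on its median.

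Within each of the 5 regions immature neuron genes fell by list mean, and in Sub a serotonin receptor gene rose. Between newborn and adult 1574 genes changed in DG (802 higher, 772 lower), 1379 in Sub (578 higher, 801 lower) and 1790 in EC (975 higher, 815 lower). In CA3 5353 changed (2745 higher, 2608 lower) and in CA1 3957 (1921 higher, 2036 lower), the 2 regions where the adult ratio was 2.74 and 2.75. With the ratio as covariate CA3 had 212 and CA1 151, but age accounts for 95.5% and 81.8% of the ratio's variance there. In DG too, where the ratio stayed low, age accounts for 76.4% of its variance. Calls in DG were 51.0% higher (45.4% as deposited, 43.7% centred on the median), in CA3 51.3% (36.7% and 27.6%), in CA1 48.5% (24.0% and 16.9%) and in Sub 41.9% (26.8% and 21.7%). From newborn to one year, when all CA3 arrays had a low ratio, 447 genes changed in CA3, 213 higher and 234 lower. In DG SOX11 fell by 3.34 and TNC by 3.04. The immature neuron list mean went from 8.998 to 7.98 in DG, 8.66 to 8.01 in CA3, 8.85 to 8.07 in CA1, 8.92 to 8.09 in Sub and 8.87 to 8.23 in EC. In Sub HTR2C, a serotonin receptor, rose by 3.31 (5.15 to 8.45, adjusted p = 4.7e-07), SPP1, osteopontin, by 2.65 and PTGDS, a prostaglandin synthase, by 2.16.

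DG stood out by genes of granule cells. GRP, the gastrin-releasing peptide gene, was 8.54-fold higher in DG than in the other regions of the same animals (adjusted p = 3.44e-17) and 2.72 log2 higher among newborns alone. In all 7392 genes differed, 3914 higher and 3478 lower (52.9% higher, and 63.2% centred on the median), and 501 with the ratio as covariate. In newborns, whose arrays all had a low ratio, 2458 differed, 1260 higher and 1198 lower. ZFPM2, a cofactor of GATA factors, was 2.23 higher (SE 0.046), ADGRG2, an adhesion receptor, 2.06 (1.10 in newborns) and BTG1, which holds back cell division, 2.06 (1.39 in newborns). The nuclear RNA MALAT1 was 1.91 higher (adjusted p = 3.11e-05), but 1.26 in newborns (adjusted p = 0.222), and 7 of 11 other probe sets moved the same way. MEIS2, a homeobox gene, was at −2.90 and RGS4, a regulator of G protein signalling, at −2.22. Granule cell markers had 11 of 13 higher and 1 lower (adjusted p = 5.98e-05; adjusted p = 0.0507 with an estimated correlation), with STXBP6 at 1.24, CALB1, calbindin, at 1.10 and SEMA5A, a semaphorin, at 0.88. Of 18 astrocyte genes 10 were higher and 3 lower, GFAP (1.57) and ALDH1L1 (1.56) among the higher (adjusted p = 0.000392, and 0.0518 with an estimated correlation). GFAP fell with age in CA1 and CA3, which enters its difference. Ribosomal protein genes had 27 of 34 higher and 2 lower (adjusted p = 4.4e-11; adjusted p = 0.137 with an estimated correlation). Myelin genes had 15 of 23 lower and 1 higher (adjusted p = 1.76e-05; adjusted p = 0.152 with an estimated correlation), and immediate early genes 9 of 14 lower and 2 higher, with NR4A2 at −1.65 and EGR1 at −1.32 (adjusted p = 0.00715; adjusted p = 0.184 with an estimated correlation).

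CA3 carried its pyramidal cell markers and, over all ages, more transcripts of the respiratory chain and sterol synthesis than the mean of the other regions. LATS2, a kinase of the Hippo pathway, was 2.07 higher in CA3 (SE 0.080, adjusted p = 4.5e-14) and 1.46 higher in newborns alone. A total of 6798 genes differed, 3663 higher and 3135 lower (53.9% higher, and 49.1% as deposited or 34.6% centred on the median), and in newborns 1756, 794 higher and 962 lower. CIB2, a calcium-binding protein gene, was 1.74 higher, NECTIN3, an adhesion protein gene, 1.56, VWA5A 1.51 (0 of 1 other probe set the same way) and LRRC10B 1.38, and in newborns 1.38, 1.08, 0.76 and 0.80. These are differences from the mean of the other regions, so a single region can lie above CA3. CAMK2D, a calcium/calmodulin kinase subunit, was at −2.16, and −1.22 in newborns. MALAT1 was at −2.11, and −2.95 in newborns. CA3 pyramidal markers had 8 of 13 higher and 2 lower (adjusted p = 0.00216, and 0.0419 with an estimated correlation), among them CPNE4 (1.37) and HS3ST4 (0.76). Cholesterol synthesis genes had 12 of 15 higher (adjusted p = 8.54e-06, and 0.0152 with an estimated correlation), with FDPS at 0.54 and INSIG1, the sterol sensor, at 0.45. In newborns alone FDPS was at 0.13 (adjusted p = 0.471). Respiratory chain genes had 31 of 40 higher (adjusted p = 4.47e-13; adjusted p = 0.071 with an estimated correlation), among them COX7A2 at 0.62 and UQCRQ at 0.50. In EC, part of the mean that CA3 is set against, 25 of 40 were lower and 2 higher (adjusted p = 5.16e-07; adjusted p = 0.113 with an estimated correlation). The difference of CA3 may thus come in part from EC. Myelin genes too had 10 of 23 higher and 1 lower (adjusted p = 0.0366; adjusted p = 0.522 with an estimated correlation).

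In CA1 leading pyramidal cell markers stood above the other regions at birth (PEX5L 1.74, POU3F1 1.82) as well as over all ages. CTXND1 was 2.02 higher (SE 0.070, adjusted p = 3.12e-15) and 2.08 in newborns, PRKCB, a protein kinase C, 1.83 and 1.48, and SH2D4B 1.80 and 1.79. GPR26, an orphan receptor, was 1.77 higher and 0.94 in newborns. SEZ6L was 2.07 higher over all ages but 0.39 in newborns (adjusted p = 0.51), and CALY, calcyon, −1.88 but −0.29 in newborns (adjusted p = 0.839). ZFPM2 was at −2.36, and −1.77 in newborns. There were 7781 genes that differed, 4022 higher and 3759 lower (51.7% higher, and 37.1% as deposited or 29.8% centred on the median), against 861 in newborns, 549 higher and 312 lower, before the CA1 ratio rose, and 297 with the ratio as covariate. CA1 pyramidal markers had 9 of 10 higher (adjusted p = 8.77e-06, and 0.00901 with an estimated correlation), with PEX5L at 1.72, the transcription factor POU3F1 at 1.20 and MPPED1 at 1.02. Postsynaptic density genes had 11 of 18 higher and 4 lower (adjusted p = 0.00189; adjusted p = 0.078 with an estimated correlation), with DLG3 at 0.87 and the calcineurin subunit PPP3CA at 0.74. Myelin genes had 14 of 23 lower (adjusted p = 6.14e-05; adjusted p = 0.243 with an estimated correlation), although MBP, myelin basic protein, at −1.63 over all ages, was at 1.10 in newborns. Of glycolysis genes 16 of 25 were lower (adjusted p = 8.77e-06; adjusted p = 0.116 with an estimated correlation), led by ALDOC (−1.77), also an astrocyte gene, which was at −0.46 in newborns (adjusted p = 0.629). Astrocyte genes had 13 of 18 lower and 2 higher (adjusted p = 6.14e-05; adjusted p = 0.078 with an estimated correlation), and complement and MHC genes 10 of 17 lower (adjusted p = 0.000385; adjusted p = 0.134 with an estimated correlation).

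Sub had higher NTS and TSHZ2 and more transcripts of myelin genes than the mean of the other regions. NTS, neurotensin, was 7.94-fold higher in Sub (adjusted p = 8.61e-11) and 2.82 log2 higher in newborns alone. Newborn CA1 lay 2.98 above the mean of its other regions, so at birth NTS did not set Sub apart from CA1. TSHZ2, a zinc finger factor, was 2.54 higher, RXFP1, the relaxin receptor, 2.53, NDST4 2.37 (1.59 in newborns; 0 of 1 other probe set the same way) and TOX 2.36 (SE 0.035, adjusted p = 2.41e-19). CALB1 was at −1.74 and KCTD4 at −1.49. In this region 4893 genes differed, 2246 higher and 2647 lower (45.9% higher, and 55.4% as deposited or 65.8% centred on the median), and in newborns 1610, 927 higher and 683 lower. Myelin genes had 20 of 23 higher and 0 lower (adjusted p = 1.36e-27, and 0.000264 with an estimated correlation), among them MOBP at 1.82, UGT8, which makes galactolipids of myelin, at 1.51 and MAL at 1.22. Oligodendrocyte precursor genes had 9 of 13 higher (adjusted p = 1.06e-06), interneuron genes 10 of 16 higher and 1 lower (adjusted p = 3.22e-05), with parvalbumin, PVALB, at 1.38. Calcium-binding genes had 6 of 12 higher and 1 lower (adjusted p = 6.04e-06), with PCP4 at 1.88 and RCAN2 at 1.35. Subicular markers had 6 of 10 higher and 2 lower (adjusted p = 0.000274, and 0.00908 with an estimated correlation), with the transcription factor TLE4 at 1.31. Markers of EC neurons stood higher in Sub as well, 7 of 12 against 1 lower (adjusted p = 6.53e-05, and 0.00733 with an estimated correlation), as did those of CA1 pyramidal cells, 5 of 10 against 3 lower (adjusted p = 0.0261; adjusted p = 0.178 with an estimated correlation).

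EC carried its neuron markers and more transcripts of interneuron and GABA-A receptor genes. CUX2, a transcription factor of upper layers, was 2.19 higher (SE 0.081, adjusted p = 1.1e-14; 0 of 1 other probe set the same way) and 1.85 higher in newborns. MEF2C was 2.14 higher, ARPP21 2.13, the vesicular glutamate transporter SLC17A6 2.11 and MEIS2 2.03 (SE 0.045). SHISA6, an AMPA receptor partner, was at −1.69 (−1.22 in newborns; 1 of 2 other probe sets the same way) and HAPLN4, which links matrix around synapses, at −1.66. Here 8218 genes differed, 3363 higher and 4855 lower (40.9% higher, and 57.4% centred on the median), and in newborns 1236, 617 higher and 619 lower. EC neuron markers had 9 of 12 higher and 2 lower (adjusted p = 1.09e-05), with ETV1 at 0.88. Interneuron genes had 11 of 16 higher and 2 lower (adjusted p = 1.44e-05), among them the GABA-making enzymes GAD1 (0.76) and GAD2 (0.75) and somatostatin, SST (0.79). GABA-A receptor genes had 8 of 10 higher and 1 lower, with GABRA4 at 0.70 (adjusted p = 0.000411). These 3 lists had adjusted p = 0.0265 each with an estimated correlation. Collagen genes had 9 of 16 higher (adjusted p = 0.000527; adjusted p = 0.16 with an estimated correlation), with decorin, DCN, at 1.41 and COL1A2 at 1.33, and 2.52 for COL1A2 in newborns. Myelin genes had 18 of 23 lower (adjusted p = 3.64e-08; adjusted p = 0.116 with an estimated correlation). Of 20 schizophrenia candidates 9 were higher and 5 lower (adjusted p = 0.0168; adjusted p = 0.16 with an estimated correlation), RGS4 (1.90), ERBB4 (0.80), a neuregulin receptor, and reelin, RELN (0.79), among the higher.

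**Figure D4:**
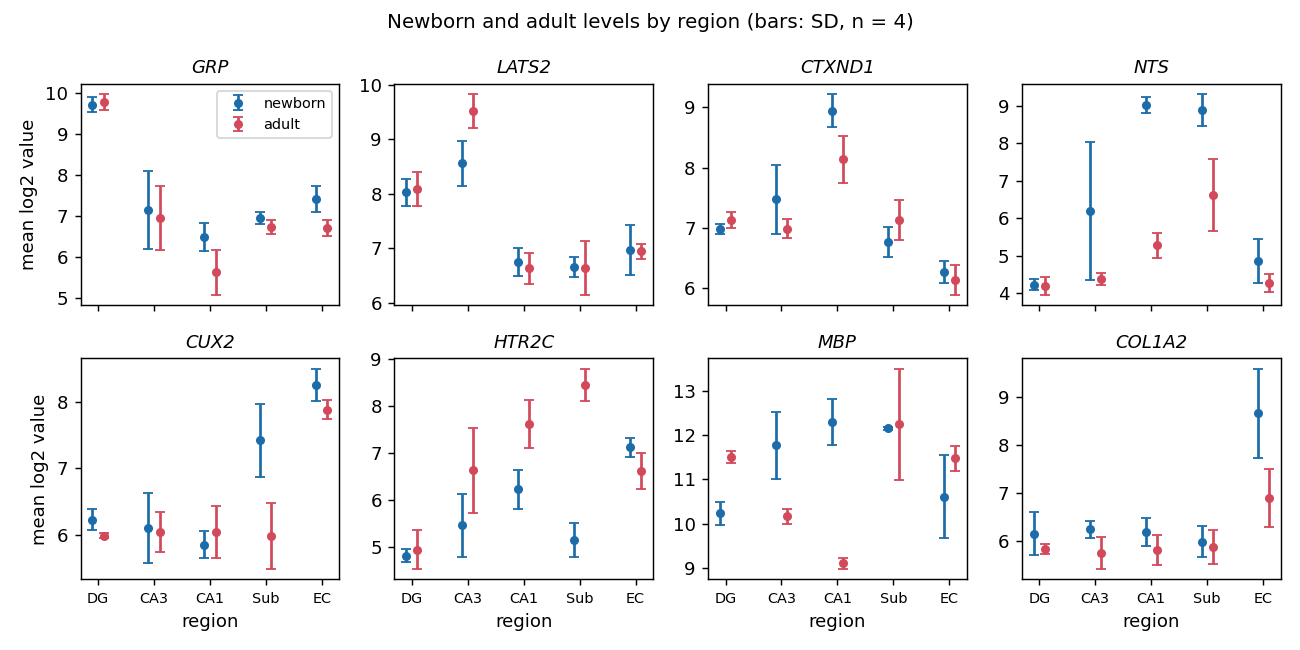
Newborn and adult log2 signal in each region for GRP, LATS2, CTXND1, NTS, CUX2, HTR2C, MBP and COL1A2. Bars are the SD over 4 animals.

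Age effects also differed between regions by the test of the difference. RNA quality could account for part of this, since CA1 and CA3 enter the mean that each other region is set against. In DG SOX11 and DCX fell further than elsewhere, and MAB21L2, a developmental gene, rose in DG by 2.17 (4.54 to 6.71), 1.99 more than in the other regions (SE 0.267, n = 4 per age). The F test of all region by age terms called 6364 genes, and 1611 among DG, EC and Sub. For DG 1493 genes differed in their age effect, 890 higher and 603 lower (59.6% higher, and 77.4% as deposited or 81.0% centred on the median), 651 against EC and Sub alone, and 708 with no replicate block. Relative to the other regions NHLH2, a bHLH factor of young neurons, fell by 2.06 more, from 7.37 to 4.66 in DG. CDC42BPA, a kinase of the cytoskeleton, fell in DG by 1.19 and rose in CA3 by 1.86, a difference from the others of −2.37, and ST18 differed by −1.999. MBP rose in DG by 1.28 and differed by 2.24, but by 0.80 from EC and Sub alone (adjusted p = 0.202), since it fell in CA1 and CA3. NTS differed by 2.08 because it was low in DG at both ages (4.23 and 4.20). Of immature neuron genes 9 of 24 had a lower age effect than elsewhere and 3 a higher one (adjusted p = 0.000581; adjusted p = 0.272 with an estimated correlation), with SOX11 at −1.67, DCX at −1.33 and MARCKSL1 at −1.06. Calcium-binding genes had 5 of 12 with a higher one (adjusted p = 0.000455, and 0.0291 with an estimated correlation), among them HPCAL4 (1.54) and PCP4 (1.64). The vesicle gene CPLX2 differed by 1.13. Myelin genes had 7 of 23 with a higher age effect (adjusted p = 0.000545, and 0.272 with an estimated correlation). So had glycolysis genes, 9 of 25 (adjusted p = 7.31e-05, and 0.272 with an estimated correlation). These lists were not rerun against EC and Sub alone. Calcium-binding and glycolysis genes had lower age effects in CA3, which is part of the mean that DG is set against. The list results therefore cannot tell a change in DG from one in CA3 or CA1.

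In CA3 LRRC10B rose more than elsewhere and calcium-binding and glycolysis genes had lower age effects, all read at an adult ratio of 2.74. LRRC10B rose in CA3 by 2.42 (7.56 to 9.98), 2.01 more than elsewhere (SE 0.225, n = 4 per age, adjusted p = 1.04e-05). FOXO6, a forkhead factor, differed by 1.64 and RPL27A, a ribosomal protein gene, by 1.94. CA11 and CA4, both of the carbonic anhydrase family, differed by −2.14 and −2.05, and PSMC3, a proteasome subunit, by −2.12. LRRC10B, RPL27A, FOXO6, CA11 and PSMC3 also changed in CA1 with the same sign, at 1.15, 2.52, 1.46, −1.84 and −2.17. For CA3 2230 genes differed, 1062 higher and 1168 lower (47.6% higher, and 31.4% as deposited or 24.7% centred on the median). Age accounts for 93.1% of the ratio's difference in CA3 and the covariate raised the SE by a median of 2.41 times, so the loss of calls with it decides nothing. With it 0 genes were called by limma, and LRRC10B was at 2.34 (adjusted p = 0.291), RPL27A at 0.41, FOXO6 at 1.06 (adjusted p = 0.378), CA11 at −0.77 (adjusted p = 0.632), PSMC3 at −0.63 (adjusted p = 0.666) and CA4 at −1.58 (adjusted p = 0.452), none of them called. Of calcium-binding genes 5 of 12 were lower and 1 higher (adjusted p = 0.000631, and 0.0334 with an estimated correlation), with CABP1 at −0.93 and HPCAL4 at −0.85. Glycolysis genes had 10 of 25 lower (adjusted p = 4.28e-06; adjusted p = 0.365 with an estimated correlation), GAPDH itself at −1.44 and ALDOC at −1.60, and complement and MHC genes 4 of 17 (adjusted p = 0.0146; adjusted p = 0.741 with an estimated correlation), with HLA-DRA at −1.10.

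In CA1 myelin genes had lower age effects than in the other regions, with a ratio that rose from 1.38 to 2.75. Over DG, EC and Sub the myelin genes called were higher in adults. MBP fell in CA1 from 12.30 to 9.10, a difference of −3.36 from the other regions (SE 0.447, n = 4 per age, adjusted p = 0.000249), with 4 of 8 other probe sets the same way. GFAP, the astrocyte filament gene, fell by 3.26 in CA1 and differed by −2.88, with 0 of 2 other probe sets the same way. Both genes also fell in CA3, by 1.61 and 1.90. NTS went from 9.03 to 5.28, a difference of −2.57 (adjusted p = 3.36e-06). NOG, the BMP blocker noggin, rose by 2.45 and differed by 2.34, RPL27A differed by 1.86 and SEZ6L by 1.76. For CA1 1480 genes differed, 629 higher and 851 lower (42.5% higher, and 14.1% as deposited or 11.6% centred on the median), from 624 to 1969 with 1 animal left out. With the ratio as covariate 30 were called, and not MBP at −1.94 (adjusted p = 0.0555), GFAP at −1.83 (adjusted p = 0.118), SEZ6L at 1.31 (adjusted p = 0.213) or RPL27A at 1.14 (adjusted p = 0.278). Myelin genes had 14 of 23 lower (16 when adjusted over the list alone; adjusted p = 4.93e-19, and 0.0476 with an estimated correlation), with MOBP at −2.32, UGT8 at −2.30, MOG at −1.90 and CLDN11, a tight junction protein of myelin, at −1.74. Precursor genes had 3 of 13 lower (adjusted p = 8.44e-05; adjusted p = 0.0729 with an estimated correlation), astrocyte genes 5 of 18 lower and 2 higher (adjusted p = 0.00844; adjusted p = 0.253 with an estimated correlation), and cholesterol synthesis genes 4 of 15 lower (adjusted p = 0.00263; adjusted p = 0.0729 with an estimated correlation), with the synthase HMGCS1 at −0.90.

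Sub gained expression of the serotonin receptor gene HTR2C. It rose in Sub by 2.76 more than elsewhere (SE 0.287, n = 4 per age, adjusted p = 7.98e-05), PTGDS by 2.01 and SPP1 by 1.87 (0 of 1 other probe set the same way). ATOH7, a proneural factor, went from 8.14 to 5.90 in Sub, a difference of −2.09, and EFNA5, an axon guidance ligand, fell there by 1.07 and differed by −1.98. RPL27A differed by −2.48 and rose in CA1, CA3 and DG. For Sub 775 genes differed, 340 higher and 435 lower, and 507 against DG and EC alone. The count ran from 339 without number 16 to 2329 without number 4, whose adult Sub array had a ratio of 2.72, and another split of the animals called 765. Astrocyte, microglia and interneuron genes had 4 of 18, 4 of 17 and 3 of 16 members with a higher age effect than the mean of the other regions and 0 with a lower one (adjusted p = 0.000128, 0.00224 and 0.00255, and 0.0287 each with an estimated correlation). That mean includes CA1 and CA3, where GFAP fell, and within Sub GFAP was at 0.48 (adjusted p = 0.502). Within Sub 3 of 18 astrocyte genes were higher in adults and 1 lower (adjusted p = 0.0167; adjusted p = 0.209 with an estimated correlation), while microglia and interneuron genes did not pass (adjusted p = 0.791 and 0.496). The differences were 0.96 for AQP4, the astrocyte water channel, 0.62 for the microglial gene C1QB and 1.17 for RELN. Myelin genes had 3 of 23 with a higher age effect (adjusted p = 0.000129; adjusted p = 0.0803 with an estimated correlation).

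TOX3, a chromatin protein gene, fell in the other 4 regions but not in EC. It was at 0.33 in EC (adjusted p = 0.388) and at −1.14 in DG, −1.01 in CA3, −1.18 in CA1 and −1.11 in Sub, a difference of 1.44 (SE 0.219, n = 4 per age). COL1A2, a fibrillar collagen, fell in EC from 8.65 to 6.89, 1.44 more than elsewhere (adjusted p = 0.00436). HTR2C differed by −1.996, with rises of 3.31 in Sub, 1.39 in CA1 and 1.17 in CA3. MBP at 1.73 (adjusted p = 0.0331), MSI2 at 1.63 (adjusted p = 0.0414) and RPL27A at −1.72 were no longer called against DG and Sub alone (0.18, 0.72 and −0.54). For EC 1657 genes differed, 923 higher and 734 lower (55.7% higher, and 80.9% as deposited or 86.1% centred on the median), but 131 against DG and Sub, and from 706 without number 4 to 2951 without number 8. No list of the 36 passed in camera for EC, the smallest adjusted p being 0.0619, while 11 had an unadjusted p under 0.05.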

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

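Tests in this part were chosen as follows. The sign shares for CA1 and CA3, the CA3 test at one year and the regroupings were set before their results were seen, while the shares of a single array, the actin values, the CA1 maturation tests, all tests of CA1 myelin and both tests of genes set apart were chosen only after. In each group of 4 the animal at 1 end was compared with the other 3 by Dixon's ratio, for GAPDH ratios, list means and named genes. Of 164 groups 11 had an animal far from the others, and chance gives about 1 in 20 groups. The myelin mean of adult CA3 was 7.12 in number 3 against 7.22 to 7.23. The blood cell mean of newborn Sub was 6.41 in number 15 against 5.87 to 5.95. The GAPDH ratio was 2.72 in adult Sub number 4 (1.18 to 1.27) and 1.77 in 6-month EC number 10 (1.24 to 1.31). Over the 5 regions adult number 3 had CCDC28A at 8.54 (8.81 to 8.83) and NREP at 10.10 (9.41 to 9.47), and adult number 4 had EFEMP1 at 9.63 (10.10 to 10.18). Newborn number 14 had BBX at 6.25 (6.51 to 6.56) and SOX11 at 7.84 (8.13 to 8.16). Newborn number 15 had RAP1GDS1 at 7.36 (9.53 to 9.94) and MYLK at 7.36 (7.20 to 7.23).

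Age effects that differed between regions, by the test of the difference itself, were found for 1493 genes in DG, 2230 in CA3, 1480 in CA1, 775 in Sub and 1657 in EC, and for 6364 genes by the F test. The log2 differences of the named genes were, in DG, MBP 2.24, NTS 2.08, MAB21L2 1.99, CDC42BPA −2.37, NHLH2 −2.06 and ST18 −1.999. In CA3 they were LRRC10B 2.01, RPL27A 1.94, FOXO6 1.64, CA11 −2.14, PSMC3 −2.12 and CA4 −2.05. In CA1 they were NOG 2.34, RPL27A 1.86, SEZ6L 1.76, MBP −3.36, GFAP −2.88 and NTS −2.57. In Sub they were HTR2C 2.76, PTGDS 2.01, SPP1 1.87, RPL27A −2.48, ATOH7 −2.09 and EFNA5 −1.98. In EC they were MBP 1.73, MSI2 1.63, TOX3 1.44, HTR2C −1.996, RPL27A −1.72 and COL1A2 −1.44.

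The CA1 and CA3 differences could come from RNA quality. Of the genes called, 89.1% in CA1 and 90.3% in CA3 had the sign seen in the 2 single arrays of other regions with a high GAPDH ratio. The shares were 16.9% in DG, 28.3% in Sub and 11.5% in EC. These low shares are no independent contrast, since DG, Sub and EC are set against a mean that includes CA1 and CA3. A bias in CA1 and CA3 gives the opposite sign in the other regions. The actin ratio goes with 3' bias in Sub number 4 (4.55 against 3.25 to 3.98) but against it in EC number 8 (2.48 against 3.78 to 4.03), yet Sub number 4 alone gave 86.4% in CA1 and 88.5% in CA3 and EC number 8 alone 84.5% and 84.1%, so 3' bias by GAPDH fits both regions, but these shares do not mark 3' bias apart from another fault of both arrays. For CA3 a regional maturation fits too: at one year, with a low ratio, 113 genes (61 higher, 52 lower) already differed from DG, EC and Sub. Of these 58 were also called in adults and 55 had the same sign. Both comparisons subtract the same newborn arrays, so the shared sign is no independent evidence. Without number 8 the one-year count was 86, under the 100 set beforehand. For CA1 maturation the first criterion used only the share of calls that stayed with the ratio as covariate, which was 1.96% and counted against it; the size of the changes was added after that share was seen, the median change being 0.728 times that without the covariate with an SE 1.32 times as large, which together cannot tell, as age accounts for 75.8% of the ratio's differences in CA1.

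Lower myelin genes in adult than in newborn CA1 (−1.03 relative to DG, EC and Sub, SE 0.154) were weighed against 3' bias, tissue content and age. In CA3 the ratio rose from one year to adult, yet the list moved by −0.0234 (SE 0.1003) where at least −0.51 was required. The rise of the ratio thus brought no such fall in CA3. A gain of myelin genes with age in CA3 could hide a loss, so this test cannot exclude 3' bias in CA1. From newborn to adult MBP by itself fell in CA3 by 1.61. Newborn CA1 pieces lay 0.57 (SE 0.114) above newborn DG, CA3 and EC, as they would if they held more oligodendrocyte-rich tissue. The precursor mean of CA1 also fell by 0.43 (SE 0.069), as fewer oligodendrocyte transcripts with age would give. CA1 number 12 at 6 months, with a ratio of 1.66, had a myelin mean of 6.70 against 7.06 to 7.68 in newborns. Dissection, age and a part of 3' bias all stay open.

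In 5 genes 1 animal lay at least 1 log2 from the other 3 of its age in all 5 regions: RAP1GDS1 (number 15, −2.43), FEN1 (number 3, −1.98), AUTS2 (number 12, −1.73), PPP1CA (number 14, 1.52) and CMC2 (number 7, 1.45). The idea came from RAP1GDS1 and took the place of tests on blood genes of number 15. With numbers permuted within region and age the highest count of 100 draws was 1, so 5 does not pass the 5-fold margin asked for, and whether such genes mark an animal cannot be told from this count alone. A sequence difference under 1 probe set fits, since 3 other probe sets of 2 of these genes deviated by a median of −0.0187 times as much. No biological explanation was tested.

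Regrouping the animals tested whether a grouping at random could give the counts. With 4 against 4 animals, 35 splits were possible. Only the real split, 1 of 35, called as many genes for adult against newborn over 5 regions (highest other 0), 6 months against newborn (20), adult against one year (25), adult against newborn in DG (0), CA3 (38), CA1 (0), Sub (43) and EC (0), and for the regional age effects of DG (0), CA3 (166), CA1 (0), Sub (765) and EC (0). A split that mixes the ages puts the real age effect into the spread, which can lower its count. For one year against 6 months the real split called 0 genes. All 35 splits therefore called as many by construction, the highest 88, and nothing follows from it. Of 100 regroupings of regions, the real one included, only the real one called as many for DG (highest other 2603), CA3 (215), CA1 (1612), Sub (4181), EC (1166) and the F test (14). For the region effects, mixing the regions likewise puts real region differences into the spread, which can lower the count.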

How the results depend on the processing

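Of the 101 gene results chosen by size and rerun, only MSI2 in EC changed sign; list members named above were not rerun singly, and the cause of a move was not tested unless stated. Whether more genes were called higher or lower did turn, in 51 of 462 pairs of a comparison and an alternative and in 12 comparisons, so no majority near even is firm. For adult against newborn in DG 51.0% were higher, but 45.4% as deposited, 43.7% centred on the median and 47.7% with the mean of all probe sets. With that mean the share went from 51.2% to 48.4% over 5 regions, from 51.3% to 47.3% in CA3, and from 51.7% to 46.7% for the CA1 region effect. For the regional age effect of CA1 it went from 42.5% to 53.9% with no replicate block and 54.6% with a random one. At 1.5-fold or more it went from 45.9% to 70.6% for the Sub region effect and from 40.9% to 71.4% for EC. The scalings, the filter on dim probe sets and the eBayes trend kept every count within 1.5 times. In DG age accounts for 55.4% of the GAPDH ratio's difference from the other regions, so calls lost there with the ratio as covariate decide little. With the GAPDH ratio as covariate, whose difference from the other regions goes with age by 75.8% in CA1 and 93.1% in CA3, so that lost calls decide little there, counts were 527 (196 higher, 331 lower) for adult against newborn over 5 regions, 162 for adult against one year, 425 in DG, 212 in CA3, 151 in CA1, 501 and 297 for the DG and CA1 region effects, 252, 0, 30 and 641 for the regional age effects of DG, CA3, CA1 and EC, and 3018 for the F test, and MSI2 in EC turned to −0.17 (adjusted p = 0.791). At 1.5-fold or more, which leaves fewer genes by construction, they were 702, 120 and 49 for adult against newborn, 6 months against newborn and adult against one year, 696, 2092, 2137, 649 and 762 within DG, CA3, CA1, Sub and EC, 766, 308, 906, 326 and 468 for the region effects, and 670, 979, 899, 395 and 762 for the regional age effects. Fitting only the 2 ages compared, with fewer samples, gave 532 for adult against one year and 749 in Sub. With a random replicate block they were 2400, 56 and 1572 for the 3 age steps, and 863 and 2364 for the regional age effects of DG and CA1. With no replicate block, run for the region effects, the regional age effects and the F test, the regional age effect of DG had 708. The 10 other counts of this setting moved by no more than 1.5 times. The mean of all probe sets gave 1004 for EC. Chosen after seeing the data, DG, EC and Sub alone gave 2612, 851, 1 and 154 for adult against newborn and the 3 steps, 651, 507 and 131 for the regional age effects of DG, Sub and EC, and 1611 for the F test, and the myelin list of 6 months against newborn turned to 0.26 (adjusted p = 9.89e-08). Without numbers 4 and 8 as well they were 2883, 2 and 57 for adult against newborn, one year against 6 months and adult against one year, with the calls of RAP1GDS1 (adjusted p = 0.507), ANXA2 (0.244), RSRC1 (0.0547) and FOS (0.0929) lost. Newborn arrays alone, also chosen afterwards and with fewer samples, gave 2458, 1756, 861, 1610 and 1236 for DG, CA3, CA1, Sub and EC. With each array centred on its median, ribosomal protein genes turned to −0.19 for adult against newborn and −0.0784 for adult against one year. For the regional age effects of DG and CA3 they turned to 0.0840 and −0.0760. Respiratory chain genes turned to −0.10 for adult against one year. Leaving out 1 animal at a time, counts ran from 996 (without 16) to 1799 (without 8) for 6 months against newborn, 0 to 5 (without 9) for one year against 6 months, 349 (without 6) to 1031 (without 12) for adult against one year, 857 (without 14) to 1697 (without 4) in Sub, 1148 (without 14) to 2712 (without 8) in EC, and 624 to 1969, 339 to 2329 and 706 to 2951 for the regional age effects of CA1, Sub and EC. Of the 101 named results, 83 stayed called with the covariate, 17 did not and 1 turned. Beside the 6 of CA3 and 4 of CA1 given above, the calls lost were ENPP2 at 0.68 (adjusted p = 0.0748), COL3A1 at −1.51 (0.117), RAP1GDS1 at 1.17 (0.587), ANXA2 at 0.96 (0.0542), MALAT1 in DG at 0.19 (0.962), CALY in CA1 at −1.09 (0.162) and MBP in EC at 0.30 (0.801). As to the rest, 98 of 101 stayed with the mean of all probe sets (not RAP1GDS1, or MBP and MSI2 in EC) and 99 of 101 with the eBayes trend (not MBP at adjusted p = 0.122 or MSI2 at 0.125 in EC). Leaving out 1 animal lost 22 named calls: ANXA2 without 1, 4, 6, 7 or 8 (adjusted p from 0.0568 to 0.0673), MBP in EC without 2, 3, 4, 13, 14 or 16, and MSI2 in EC without 1, 2, 3, 4, 9, 10, 12, 13, 14, 15 or 16. Signal over background limits dim genes, since a probe near the floor of the array shows small changes only.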

Other observations

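Single hormone and imprinted genes changed, in lists that did not pass. CRH, the corticotropin-releasing hormone gene, fell from newborn to adult by 1.26 (adjusted p = 2.94e-08) and by 1.30 over DG, EC and Sub. DIO2, the enzyme that activates thyroid hormone, fell by 0.92 (adjusted p = 2.02e-08), while the thyroid hormone receptor THRB rose by 0.67 and FKBP5, a partner of the glucocorticoid receptor, by 0.70. The steroid and thyroid list, with 16 members measured, had 3 higher and 3 lower (adjusted p = 0.995), and its median of 0.05 and mean of −0.04 differed in sign. Of imprinted genes NNAT, neuronatin, fell by 1.29 and MEST by 0.90, and PEG3 rose by 0.61, with 5 of 16 lower and 2 higher (adjusted p = 0.309).

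Immediate early genes rose from newborn to 6 months in EC (2 of 14 called higher, adjusted p = 7.74e-06) and Sub (3 higher, adjusted p = 0.000589), and fell from one year to adult (adjusted p = 0.000204 and 0.0127). With an estimated correlation none of these 4 passed (0.0516, 0.0956, 0.272 and 0.448), and the list did not pass between 6 months and one year (adjusted p = 0.429 and 0.835). Their mean in EC was 7.28, 7.63, 7.52 and 7.21 at newborn, 6 months, one year and adult, and in Sub 7.22, 7.55, 7.53 and 7.20 (n = 4 each). In CA3 it was 7.14, 7.14, 7.20 and 7.14. JUN rose from newborn to adult by 0.58 over 5 regions and FOS fell by 0.59.

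Newborn number 15 had the highest blood list mean of its age in every region, at 6.30 in DG, 6.81 in CA3, 6.35 in CA1, 6.41 in Sub and 6.30 in EC. HBB was 1.80, ALAS2 0.55 and HBD 0.38 above the mean of the other newborns, each highest in 5 of 5 regions, while SLC4A1, the carbonic anhydrase gene CA1 and EPB42 were at −0.01, 0.02 and −0.03.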
